A study of Rattus norvegicus with 3 samples.

How the data were processed

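The values analysed here are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library), the unit that stands in the file headers, computed by the authors. No reads were processed here. According to the labels, RNA was extracted with Trizol and cleaned on RNeasy columns with DNase treatment. From 10 µg of total RNA, poly(A) RNA was selected, fragmented chemically and reverse transcribed from random primers. Libraries went through 15 cycles of PCR and size selection on a gel, and each was sequenced as paired-end reads of 51 bases in 1 lane of a Genome Analyzer II. Random priming and fragmentation spread reads over the transcript, which suits a value per kilobase. Poly(A) selection leaves out transcripts without a tail.

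Per the submitters' processing notes, the tools were TopHat 1.3.1 and Cufflinks 1.2.0 and the genome build was rn4. Their options, the handling of reads that map to several places, trimming, duplicate removal and filters are not given in the sources used here. Such steps can change the measured values: reads shared by near-identical copies of a gene may be dropped or divided, and FPKM is scaled to the total of each library, so a few very abundant transcripts lower the rest. The 20 highest genes held 9.71% of all FPKM in the pineal day library, 9.43% in the night library and 10.99% in the mixed-tissue library. PCR duplicates, if kept, make counts look more precise than they are.

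The deposited tables held 17089 entries, 16932 for RefSeq transcripts and 157 for unnamed regions with an identifier that starts with PFAR, whose meaning is not given in the sources used here. The table of the whole series and the files per sample were identical in 51267 of 51267 values. Entries that share a symbol, 802 entries of 342 symbols, were summed, which left 16629 genes and regions. Pde4d is the 1 symbol with entries on several chromosomes, so its sum is uncertain. Another 24 symbols had been turned into dates, as spreadsheet programs do. They are counted but not named. Coordinates are those of the tables, on rn4, with starts counted from 1. Interval bounds, counts and status flags were not used here.

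Sequencing depth is not given as a number of reads. It was estimated from 1337 single-exon receptor gene models with spans from 800 to 1100 bp, most of which are listed at 0. Their smallest values above 0, multiplied by length, repeat at steps of 1 fragment. The step was 0.114 FPKM kb in the day library (22 models), 0.189 by night (4 models) and 0.103 in the mixed tissues (23 models), and values at 2 fragments were 1.97, 1.76 and 2.03 times the step. This gives 8.74, 5.29 and 9.73 fragments per kb at 1 FPKM, or a depth of 60.5% for the night library and 111.4% for the mixed tissues relative to the day library. The night value rests on few models. A floor of 3 fragments on 1 kb corresponds to 0.34, 0.57 and 0.31 FPKM. Exact Poisson bounds for a 1 kb transcript at 1 FPKM are 0.47 to 1.95 by day, 0.31 to 2.21 by night and 0.49 to 1.89 in the mixed tissues, and at 20 FPKM 17.2 to 23.2, 16.4 to 24.2 and 17.3 to 23.1. These bounds cover counting error alone, not differences between animals.

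The libraries listed 3992 (day), 4378 (night) and 2877 (mixed) genes at 0, and 9581, 9392 and 11682 at FPKM of at least 1. Each comparison used the log2 ratio of FPKM + 1 for genes with FPKM of at least 1 in at least 1 of the 2 libraries. The counts describe genes at least 2-fold apart for night against day and at least 4-fold apart against the mixed tissues. With 1 library per group no p-value was computed. The share of genes higher by night carries a 95% Wilson interval, which treats genes as independent.

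The 38 gene lists were written before the data were examined: 16 pathway lists, 1 list of reference genes, 11 lists of cell type markers and 10 lists of markers of the pooled organs. They hold 496 entries, 475 different symbols, of which 442 were found in the tables. For each list the median log2 ratio was set against 10000 random lists of the same size, matched on mean log2(FPKM + 1) in 20 bins, and its percentile is given. The percentile describes these libraries and is not a test across animals. With 38 lists in 3 comparisons, some medians outside the central 95% of random lists are due by chance.

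Named genes follow a rule set before the data were examined. It takes the 12 highest and 12 lowest log2 ratios among genes with FPKM of at least 5 in the higher library, or 10 and 10 for the night against mixed comparison. Small RNA genes, models under 300 bases, mitochondrial genes and identifiers without an official-looking symbol were left out for naming. From the lists of melatonin synthesis, clock genes, phototransduction, fast-responding genes and transcription factors, the 4 members with the largest ratios and any member at least 2-fold apart may be named, and up to 4 members of any other list. The 10 most abundant genes of each library may also be named. Other genes and regions named, including the examples of near-0 values and the Hedgehog genes, were chosen after their values were seen. Gnas, Hspa8 and Hsp90aa1, whose low values may be failed estimates, are given as uncertain but stay in the counts of their lists. Some genes that the rule would name, and the results that need them, are not reported here.

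Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a filter at FPKM 5, 3 rescalings of the libraries (median ratio of 0, upper quartile, and the sum without the 20 highest genes), leaving out 403 small RNA genes and short models, taking the highest entry per symbol, the series table, and other size thresholds. A filter at FPKM 20 and leaving out unnamed regions were added after seeing the data.

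The code was tested on simulated data with counting error only, on all 16629 genes and regions. For night against day, true 2-fold differences passed the 2-fold threshold in 32.0% of 50 genes (median log2 0.93), and 4-fold, 8-fold and 16-fold differences in 100.0% each (1.96, 2.92 and 3.76), while 0.38% of 9614 unchanged genes passed. For day against mixed tissues at 4-fold, the shares were 0.0%, 18.0%, 98.0% and 100.0% for the 4 sizes (median log2 0.92, 1.85, 2.67 and 3.72), and for night against mixed tissues 0.0%, 36.0%, 100.0% and 100.0% (0.97, 1.89, 2.86 and 3.75), with 0.0% of 11451 and 11388 unchanged genes. Lists of 15 genes with a true 2-fold shift left the range of random lists in 20 of 20 simulations per comparison and unchanged lists in 0 of 20. The ratios come out below the true sizes because of the pseudocount, and genes near a size threshold are counted less often than they should be.

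Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene names and named pseudogenes were taken from a newer RefSeq gene table, which was used for names and not for coordinates.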

Results

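The data set held 3 poly(A) RNA libraries of adult Sprague-Dawley rats kept under 14 h of light and 10 h of dark. Pineal glands were taken by day at zeitgeber time 7 (hours after lights on) and by night at zeitgeber time 19, in the dark. The remaining library, also from zeitgeber time 7, pooled equal amounts of RNA from 15 tissues outside the pineal gland: liver, kidney, lung, heart, small intestine, skeletal muscle, adrenal gland, pituitary, retina, spinal cord, cerebellum, hindbrain, midbrain, hypothalamus and cortex. Each group had 1 library, so there are no replicates: the differences below have no replicate check and are described by their size, without p-values. Values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library) as deposited, and ratios are log2 ratios of FPKM + 1. This scale understates the fold change of genes with low values. A gene was compared where FPKM reached 1 in at least 1 of the 2 libraries concerned. Most choices below, including the 38 gene lists and the rule for naming genes, were made before the data were examined.

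Tph1, which encodes tryptophan hydroxylase, the enzyme that opens the path from tryptophan to serotonin and melatonin, was the most abundant transcript of both pineal libraries, at 4665 FPKM by day and 4245 by night (2.22% and 1.98% of all FPKM). Photoreceptor G protein subunits followed among the 10 highest genes: Gngt1 (1128 by day, 1828 by night), Gnb3 (1088 and 1027) and Gngt2 (1053 and 1017). So did Snap25, a membrane fusion protein of secretory vesicles (1213 and 1217), Apoe, a lipid carrier (1040 and 917), Ptprn, a protein of dense-core vesicles (946 and 782), and Cd63, a tetraspanin of endosomes (920 and 893). Plekhb1 (865) and Gpx4 (854), a glutathione peroxidase, completed the day library's list. By night their places went to Bcat1, a branched-chain aminotransferase (872), and Aanat (762). The mixed-tissue library was led by transcripts of its source organs: Gh1 (5891 FPKM, growth hormone), Mbp (2720, myelin basic protein), Alb (2030, albumin), Scgb1a1 (1449, an airway secretory protein), Acta1 (1440, skeletal muscle actin), Prl (1244, prolactin), Apoe (1064) and Hbb (1024, haemoglobin).

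By night, Aanat, which encodes the enzyme that acetylates serotonin on the way to melatonin, stood at 762 FPKM against 5.34 by day (log2 ratio 6.91; chr10:106709371-106713683, rn4). The largest ratio was that of Slc15a1, a peptide transporter, with 287 FPKM by night and 0.220 by day (log2 7.88; chr15:106550096-106592594). The values of Slc15a1, and of Crem below, are sums of 2 entries, so they do not tell which form of the transcript differed. Other genes at the top of the ranking were Dio2, the deiodinase that activates thyroid hormone (76.8 by night and 0.464 by day, log2 5.73), Dusp1, a phosphatase of MAP kinases (237 and 3.61, log2 5.69), Irs2, an adaptor of insulin signalling (130 and 2.30, log2 5.31), and Crem, a transcription factor of the cAMP response (428 and 12.1, log2 5.04). In the opposite direction, Sgk1, a serum and glucocorticoid-regulated kinase, was at 10.1 FPKM by night and 64.8 by day (log2 -2.57), and Arntl, the clock activator also called Bmal1, at 2.08 and 11.8 (log2 -2.05). Of 9826 genes and unnamed regions compared, 411 were at least 2-fold higher by night and 207 at least 2-fold lower, while 93.7% lay within 2-fold (median log2 ratio -0.11).

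The remaining genes among the 12 highest night over day ratios were Zrsr1, a splicing factor gene (384 FPKM by night and 9.16 by day, log2 5.25), Atp7b, a copper-transporting ATPase (132 and 2.52, log2 5.24), the kinase gene Dclk3 (133 and 2.56, log2 5.24), Sik1, a salt-inducible kinase (97.8 and 1.72, log2 5.18), Cited4, a transcriptional coregulator (26.8 and 0.239, log2 4.49), and Ptch1, the Hedgehog receptor (233 and 11.2, log2 4.27). On the FPKM + 1 scale the asymmetry was wider at 4-fold, with 124 higher and 11 lower, and at 8-fold 47 were higher and 0 lower. This scale narrows the ratios of genes with low values. In FPKM alone, Sstr3 was 15.6-fold and Nxnl2 12.2-fold lower by night. Counts at these sizes were not rerun with another pseudocount. Of the 124, 88 were at least 4-fold above the mixed tissues by night but 9 by day, and 10 were at least 4-fold below them by day. The 124 were chosen by their night over day ratio, so a drop by day against the same mixed library follows from that choice.

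**Figure D1:**
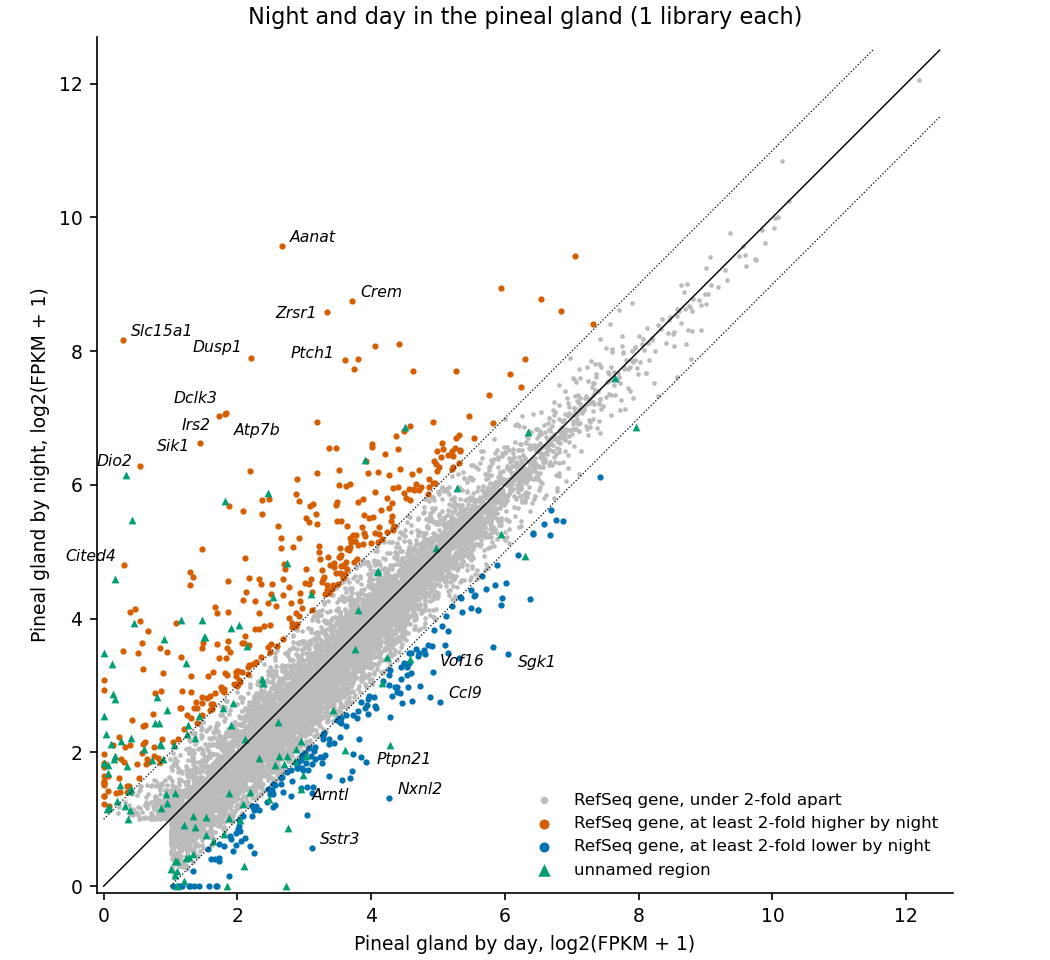
Pineal night against pineal day, each point a gene or unnamed region compared, on log2(FPKM + 1) axes; dotted lines mark 2-fold, orange and blue points are RefSeq genes at least 2-fold higher or lower by night, green triangles are unnamed regions, and some of the genes named in the text are labelled. There is 1 library per axis, so the scatter shows no replicate spread.

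Genes that respond fast to cAMP or other stimuli were the list furthest above the rest by night: 16 of 21 were at least 2-fold higher, 0 lower and 5 within 2-fold. Their median log2 ratio was 2.23, at percentile 100 of 10000 random lists matched on expression level. Besides those above, they included the orphan nuclear receptors Nr4a1 (72.6 FPKM by night and 3.58 by day, log2 4.01), Nr4a3 (16.2 and 0.312, log2 3.71) and Nr4a2 (6.47 and 1.48, log2 1.59), Rgs2, a brake on G protein signalling (122 and 8.13, log2 3.75), and Egr1, an early growth response factor (32.5 and 6.13, log2 2.23). Junb (log2 2.03), Btg2 (1.79), Ier2 (1.28) and Ier3 (1.08) were also past 2-fold. Of 14 cyclic nucleotide phosphodiesterases, a list that shares Pde4b and Pde4d with the first, 5 were at least 2-fold higher, 0 lower and 9 within 2-fold (median 0.47, percentile 100). Pde10a was at 47.6 FPKM by night and 3.26 by day (log2 3.51), Pde4b at 93.1 and 9.29 (log2 3.19), Pde4d at 22.7 and 2.64 (log2 2.71) and Pde8b at 21.9 and 4.09 (log2 2.17).

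Among 15 clock genes and clock outputs, 7 were at least 2-fold higher by night, 1 lower and 7 within 2-fold (median 0.69, percentile 100). The repressors Per1 (40.6 FPKM by night and 5.11 by day, log2 2.77), Cry2 (63.9 and 11.8, log2 2.34), Per2 (6.38 and 0.706, log2 2.11) and Per3 (28.7 and 12.9, log2 1.10) were higher. So were the clock output Dbp (89.8 and 39.2, log2 1.17), Bhlhe40 (20.8 and 9.69, log2 1.03) and RGD1566380, listed in the reference as Ciart (2.55 and 0.558, log2 1.19). Arntl was the member that was lower.

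Chaperones and stress factors formed another group on the night side. Of 22 members, 10 were at least 2-fold higher, 0 lower and 12 within 2-fold (median 0.81, percentile 100). They included the heat shock genes Hspa1a (71.2 FPKM by night and 8.08 by day, log2 2.99), Hspa1b (11.5 and 1.81, log2 2.15), Dnajb1 (92.1 and 20.2, log2 2.14) and Hsph1 (162 and 53.5, log2 1.58). The 10 also take in Hspa8 (2.08 and 0.167, 33 named copies in the reference) and Hsp90aa1 (6 and 1.93, 16 copies), whose low values are uncertain.

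In the melatonin pathway, 1 of 4 genes was past 2-fold. Besides Aanat, Ddc, the decarboxylase that makes serotonin, was at 288 FPKM by night and 171 by day (log2 0.75), Asmt, the last enzyme, at 506 and 395 (log2 0.36), and Tph1 at a log2 ratio of -0.14 (list median 0.55, percentile 97.8, or 97.4 with a filter at FPKM 5, inside the range of random lists). The methionine cycle, which supplies the methyl donor used by Asmt, had 1 of 9 members past 2-fold, the S-adenosylmethionine synthetase gene Mat2a (53.3 and 6.60, log2 2.84), and a list median of -0.06 (percentile 62.8). The 6 genes of the tetrahydrobiopterin cofactor of tryptophan hydroxylase lay within 2-fold (median -0.03, percentile 63.2).

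Transcription factors of the pineal gland and photoreceptors were split. Bsx, a homeobox gene, was at 493 FPKM by night and 60.6 by day (log2 3.01), and Isl2, a LIM homeobox gene, at 37.2 and 102 (log2 -1.42). Another 9 of the 11 lay within 2-fold, among them Rax (6.92 and 14.2, log2 -0.94) and Lhx4 (389 and 207, log2 0.91), and the list median was 0.29 (percentile 98.8). Of 26 phototransduction genes, 24 were within 2-fold (median -0.20, percentile 1.83). Sag, the rod arrestin, was higher by night (337 and 158, log2 1.09) and Gucy2e, a retinal guanylate cyclase, lower (6.48 and 19.9, log2 -1.48). Pdc, phosducin, followed with 235 and 440 (log2 -0.91). This list no longer stood apart from random lists with a filter at FPKM 5 (percentile 11, median -0.11) or a pseudocount of 0.1 (percentile 2.53).

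Noradrenaline receptors and their second messenger enzymes had 14 of 15 members within 2-fold and a median of 0.21 (percentile 99.1). Adra1b (60.1 FPKM by night and 33.9 by day, log2 0.81) and Adrb1 (133 and 84.7, log2 0.64) encode receptors, and Adcy1 (8.24 and 29.3, log2 -1.72), an adenylate cyclase, was the member past 2-fold, on the lower side. In the list of ribbon synapse and vesicle release genes, 17 of 20 were within 2-fold (median 0.08, percentile 95.1, or 0.26 and 98.7 with the libraries centred). Slc17a6, a vesicular glutamate transporter, was at 117 by night and 22.8 by day (log2 2.30), Cplx2, a complexin, at 3.58 and 0.834 (log2 1.32), and Cabp4, a calcium-binding protein of photoreceptor synapses, at 9.59 and 38.9 (log2 -1.91). All 18 cholesterol synthesis genes lay within 2-fold, with a median of 0.18 (percentile 99.7) that became 0.07 (percentile 93.6) with a filter at FPKM 5.

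Lists nearer the bulk of genes were thyroid hormone handling (1 higher, Dio2, and 5 within 2-fold, median 0.19, percentile 93.9), retinoid metabolism (15 of 16 within, median -0.19, percentile 23.1, with Rara, a retinoic acid receptor, at 2.41 and 6.49, log2 -1.13), and glycolysis (15 of 16 within, median -0.01, percentile 66.7, with Hk2, hexokinase 2, at 8.71 and 20.8, log2 -1.16). Cell cycle genes had 7 of 8 within 2-fold (median -0.31, percentile 15.5, or 0.29 for the 2 members left by a filter at FPKM 5), and Pcna, a replication clamp, was at 61.8 by night and 25.7 by day (log2 1.24). The 13 reference genes compared were within 2-fold, with a median of 0.00 (percentile 75.6). Gapdh and Ppia, listed near 0, fell below the filter and were not among them. Rpl13a, at 1.70 FPKM by night and 0.462 by day, was within 2-fold only on the FPKM + 1 scale.

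Markers of cell types were compared in the same way. Pinealocyte markers had 3 of 11 at least 2-fold higher by night and 0 lower (median 0.70, percentile 100), namely Aanat, Bsx and Sag, so that list does not measure the share of pinealocytes. The 10 fibroblast and meningeal markers had a median of -0.36 (percentile 0.49), with Col3a1 at 43.3 FPKM by night and 64.7 by day, and the 6 astrocyte markers -0.41 (percentile 2.37), with Gfap at 5.16 and 10.2, 0 of them past 2-fold. The astrocyte list was inside the range of random lists with a pseudocount of 0.1 (percentile 3.23) or a filter at FPKM 5 (percentile 2.56). Oligodendrocyte markers stood at -0.50 (percentile 3.88, 1 of 5 lower, Cnp at 7.93 and 18.2), mural cell markers at -0.41 (percentile 6.19), erythroid markers at -0.34 (percentile 7.55) and endothelial markers at -0.29 (percentile 24.1). Neuron (0.01, percentile 69.5), microglia (0.05, percentile 89.9), choroid plexus (0.10, percentile 88.9) and leukocyte lists (0.03, percentile 74.8) stayed near 0. In the last of these Fcer1a, the alpha chain of the high-affinity IgE receptor, was at 235 by night and 12.9 by day (log2 4.08). Markers of the mixed tissues were little expressed in the gland, so that 0 to 2 members of each such list could be compared: liver (Serpina1 at 2.52 and 6.42, log2 -1.07), heart -0.10, lung -0.47, pituitary 0.36, adrenal gland 0.27, cerebellum -0.13 and hypothalamus -0.29, and no member for skeletal muscle, kidney and intestine.

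The lowest night over day ratios belonged to Nxnl2, a thioredoxin-like gene of photoreceptors (1.49 FPKM by night and 18.2 by day, log2 -2.95), Sgk1, and Sstr3, a somatostatin receptor (0.490 and 7.64, log2 -2.54). Next were the chemokine gene Ccl9 (5.74 and 31.6, log2 -2.27), Vof16 (10.9 and 55.7, log2 -2.26), the tyrosine phosphatase gene Ptpn21 (2.61 and 14.2, log2 -2.08), Ndrg1 (18.7 and 81.8, log2 -2.07) and Rgs20, a regulator of G protein signalling (6.14 and 28.5, log2 -2.05). P2ry4, a nucleotide receptor (2.30 and 12.2, log2 -2.0), Dennd2c (1.09 and 7.22, log2 -1.98) and Wdr89 (2.02 and 10.8, log2 -1.96) closed the 12. Of the 207 lower by night, 32 were at least 4-fold above the mixed tissues by day.

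Besides RefSeq genes, the tables listed 157 unnamed regions, of which 124 could be compared. Their median log2 ratio was 0.65, with 54 at least 2-fold higher by night, 18 lower and 41.9% within 2-fold, against 94.4% of RefSeq genes. How the regions were chosen is not given in the sources used here. If they were picked from these libraries, the difference from RefSeq genes may only restate that choice. The following regions were chosen after their values were seen. PFAR1 (chr12:5279390-5288650) was at 69.8 FPKM by night and 0.256 by day (log2 5.82), PFAR20 (chr8:115797800-115830300) at 43.6 and 0.337 (log2 5.06), and PFAR4 (chr15:106554430-106567170) at 23.0 and 0.126 (log2 4.42). PFAR20 ends 172 bp from the span of Dclk3, and PFAR4 lies inside the span of Slc15a1. Without the unnamed regions, 357 RefSeq genes were at least 2-fold higher and 189 lower.

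The night library was the shallowest, at an estimated 60.5% of the depth of the day library, so that a 1 kb transcript at 5 FPKM has 95% counting bounds of 3.21 to 7.20 by night and 3.66 to 6.76 by day. The split between higher and lower depends on low values: a pseudocount of 0.1 gave 533 higher and 518 lower, one of 5 gave 231 and 64, and a filter at FPKM 20, added after the data were seen, gave 208 and 63.

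Set against the mixed tissues at the same time of day, the genes of highest ratio in the pineal gland included enzymes of melatonin synthesis and several phototransduction genes known from cones. Tph1 was at 4665 FPKM in the gland and 0.309 in the mixed tissues (log2 11.80; chr1:97186071-97207551), and Asmt at 395 and 1.45 (log2 7.34; chr12:16811892-16817186). Gnat2, the cone transducin alpha subunit, was at 777 and 6.35 (log2 6.72; chr2:203652354-203661377), whereas Gnat1, its rod counterpart, was at 1.59 and 355 (log2 -7.10). Of 11934 genes and regions compared, 273 were at least 4-fold higher in the gland by day and 1581 at least 4-fold lower, with a median log2 ratio of -0.27.

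All 4 melatonin genes were at least 4-fold higher (median 5.53, percentile 100), including Ddc (171 FPKM and 12, log2 3.73) and, even by day, Aanat (5.34 and 0.134, log2 2.48). Other genes among the 12 highest were Chrnb4, a nicotinic acetylcholine receptor subunit (211 and 0.362, log2 7.28), the homeobox genes Lhx4 (207 and 0.816, log2 6.84), Isl2 (102 and 0.319, log2 6.28) and Bsx (60.6 and 0.0851, log2 5.83), and Col8a1, a collagen chain (171 and 1.32, log2 6.21). Gngt2 (1053 and 9.71, log2 6.62), Pde6c (156 and 1.10, log2 6.22), Gnb3 (1088 and 14.2, log2 6.16) and Opn1sw, the short-wave cone opsin (112 and 1.08, log2 5.77), belong to the cone light response.

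Over the whole phototransduction list, 11 of 30 genes were at least 4-fold higher in the gland, 7 lower and 12 within 4-fold (median 1.48, percentile 100). The lower members included, besides Gnat1, the rod phosphodiesterase subunits Pde6a (0.985 FPKM and 63.7, log2 -5.03) and Pde6b (2.75 and 55.7, log2 -3.92), and Abca4 (0.443 and 12.9, log2 -3.26). Rcvrn, recoverin, was at 2.27 and 105 (log2 -5.02), and Opn1mw, the middle-wave cone opsin, was listed at 0 in both pineal libraries and at 3.57 in the mixed tissues. Pde6h, a cone phosphodiesterase subunit, was also below the mixed tissues (1.22 and 7.46, log2 -1.93), so cone genes were not all on the higher side. Higher members also took in Aipl1 (368 and 51.3, log2 2.82), Cngb1 (55.7 and 9.02, log2 2.5), Grk1, a photoreceptor kinase (90.7 and 16.4, log2 2.40), Rgs9 (82.1 and 16.1, log2 2.29), Gngt1 (1128 and 273, log2 2.04) and Guca1b (240 and 58.5, log2 2.02). Cngb1 and Gngt1 are known from rods, so rod genes were found on both sides.

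**Figure D2:**
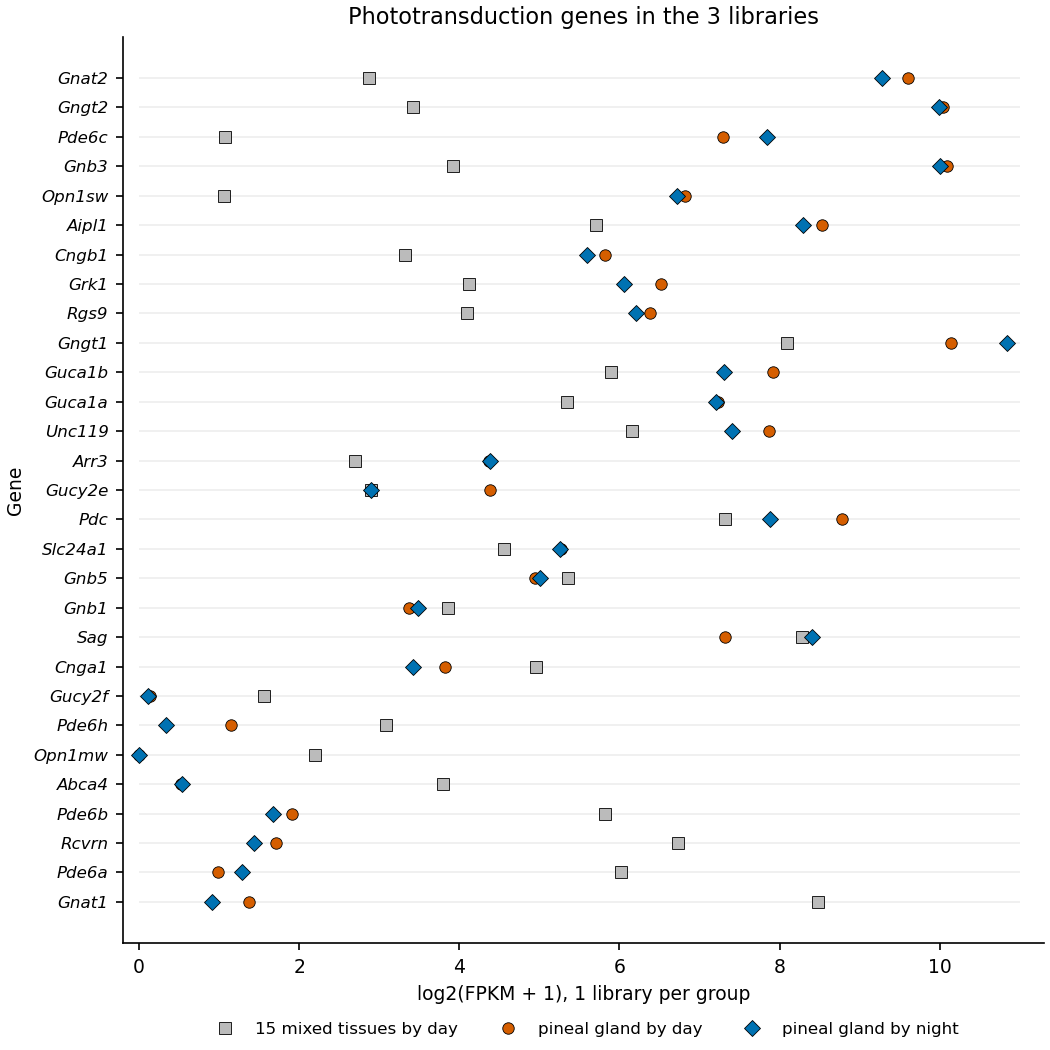
FPKM of phototransduction genes in the pineal day, pineal night and mixed-tissue libraries on a log2(FPKM + 1) axis, 1 library each. The mixed tissues contain retina as 1 of 15 equal parts, so rod transcripts appear there.

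Among 17 transcription factors of the pineal gland and photoreceptors, 9 were at least 4-fold higher, 3 lower and 5 within 4-fold (median 2.17, percentile 100). Mitf (77.6 FPKM and 2.12, log2 4.66), Neurod4 (193 and 6.81, log2 4.63), Otx2 (189 and 19.7, log2 3.20), Crx, the cone-rod homeobox gene (237 and 31.5, log2 2.87), Neurod1 (138 and 29.4, log2 2.19) and Pax4 (40.6 and 8.24, log2 2.17) joined Lhx4, Isl2 and Bsx. Nrl, the leucine zipper factor of rods, was at 0.407 and 41.5 (log2 -4.92), Tbx2 at 0.643 and 7.93 (log2 -2.44) and Six3 at 0.110 and 4.53 (log2 -2.32).

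Ribbon synapse and vesicle genes had 4 of 21 at least 4-fold higher, 4 lower and 13 within (median 0.47, percentile 99.1), and the complexins diverged: Cplx3, the form of retinal ribbon synapses, was at 181 FPKM and 8.02 (log2 4.34), while Cplx1 (0.555 and 126, log2 -6.35) and Cplx2 (0.834 and 48.0, log2 -4.74) were far lower. Gch1, which makes the cofactor of tryptophan hydroxylase, was at 366 and 5.77 (log2 5.76) and its regulator Gchfr at 0.293 and 15.0 (log2 -3.63), in a cofactor list split 2 higher, 1 lower and 4 within (median -0.01, percentile 70.8). The adrenergic list had 2 higher, Adrb1 (84.7 and 2.74, log2 4.52) and Adra1b (33.9 and 3.56, log2 2.94), 3 lower, of which Gnas is uncertain, and 17 within (median -0.60, percentile 19.5). With a filter at FPKM 5 the median of this list turned to 0.37 (percentile 92.6). Phosphodiesterases had 1 higher, Pde1c (29.6 and 1.97, log2 3.36), 2 lower and 13 within (median -1.08, percentile 4.26). In retinoid metabolism, Rxrg, a retinoid X receptor (109 and 5.81, log2 4.01), and Rbp3, the retinoid-binding protein of the photoreceptor matrix (406 and 40.4, log2 3.30), were the 2 higher, against 4 lower, such as Rbp2 (0.120 and 104, log2 -6.55), and 16 within (median -0.50, percentile 29.4).

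Cholesterol synthesis and uptake was the pathway list furthest below the mixed tissues: 0 of 21 at least 4-fold higher, 9 lower and 12 within (median -1.78, percentile 0.00). Dhcr7 (1.41 FPKM and 23.1, log2 -3.32) encodes a late enzyme and Hmgcs1 an early one (11.8 and 114, log2 -3.17). The fast-responding genes, so high by night, were below the mixed tissues by day, with 0 higher, 3 lower at 4-fold and 20 within (median -1.14, percentile 0.70). Dusp1 was at 3.61 and 39.1 (log2 -3.12), Klf4 at 0.799 and 7.68 (log2 -2.27) and Nr4a1 at 3.58 and 19.8 (log2 -2.18).

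The other pathway lists stayed inside the range of random lists. All 15 clock genes (median -0.16, percentile 55), all 21 chaperones and stress factors (median -0.44, percentile 8.31) and all 15 cell cycle genes (median -0.76, percentile 47.4, or 0.51 for the 2 members left by a filter at FPKM 5) were within 4-fold. The methionine cycle had 2 of 9 lower, Adk (2.98 FPKM and 34.6, log2 -3.16) and Shmt1 (0.537 and 6.88, log2 -2.36), with a median of -0.07 (percentile 64.7). Thyroid hormone handling had 2 of 8 lower, Dio1 (listed at 0 in the gland and at 11.9) and Slco1c1 (0.595 and 14.1, log2 -3.24; median -1.0, percentile 13.0). Glycolysis had 3 of 17 lower, Pfkp (2.40 and 54.7, log2 -4.03), Slc2a3 (0.250 and 12.2, log2 -3.40) and Aldoc (39.1 and 309, log2 -2.95), with a median of 0.19 (percentile 81.5). Of 12 reference genes, 11 were within 4-fold and Tfrc lower (4.96 and 27.8, log2 -2.27; median -0.13, percentile 47.9).

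Markers of other cells and organs were lower. Neuron markers had 9 of 12 at least 4-fold lower, 1 higher and 2 within (median -4.57, percentile 0.00), with Nefl, a neurofilament, at 0.0688 FPKM and 154. All 8 oligodendrocyte markers were lower (median -5.92, percentile 0.01), among them Mbp (5.17 and 2720), and 4 of 6 astrocyte markers (median -3.32, percentile 0.58), among them Gfap (10.2 and 165). Endothelial (3 of 7 lower, median -1.46, percentile 1.34), mural (1 of 7, -1.26, percentile 3.36), erythroid (median -1.33, percentile 6.72), microglia (2 of 11, -0.85, percentile 8.27) and leukocyte lists (1 higher and 1 lower of 6, -1.25, percentile 11.2) lay less far down. Choroid plexus (median -0.38, percentile 50.9) and fibroblast markers (0 of 10 past 4-fold, median -0.27, percentile 24.5) were close to the bulk. Pinealocyte markers had 9 of 11 higher and 1 lower, Rcvrn (median 2.87, percentile 100). Most of these markers also belong to the melatonin, phototransduction or transcription factor lists. The list therefore largely repeats those results, here and in the other comparisons.

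Lists of the pooled organs had medians far below 0: skeletal muscle -8.94 (8 of 8 at least 4-fold lower), heart -7.52 (7 of 7), pituitary -7.33 (7 of 7), lung -7.24 (5 of 5), liver -6.87 (9 of 9), intestine -5.37 (4 of 4), kidney -4.83 (6 of 6), cerebellum -4.46 (4 of 6), adrenal gland -3.11 (5 of 7, with Chga higher at 421 FPKM and 85.6) and hypothalamus -2.91 (4 of 6). The lowest single genes were of this kind. Gh1 (5891), Alb (2030), Scgb1a1 (1449), Prl (1244), Sftpc, a lung surfactant protein (1022), Ckm, muscle creatine kinase (796), Myl1 (659) and Myl2 (535), myosin light chains, and Pvalb, parvalbumin (552), were listed at 0 in the pineal day library. Acta1 (0.114 FPKM and 1440, log2 -10.34) and Mylpf (0.494 and 959, log2 -9.33) had traces there.

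**Figure D3:**
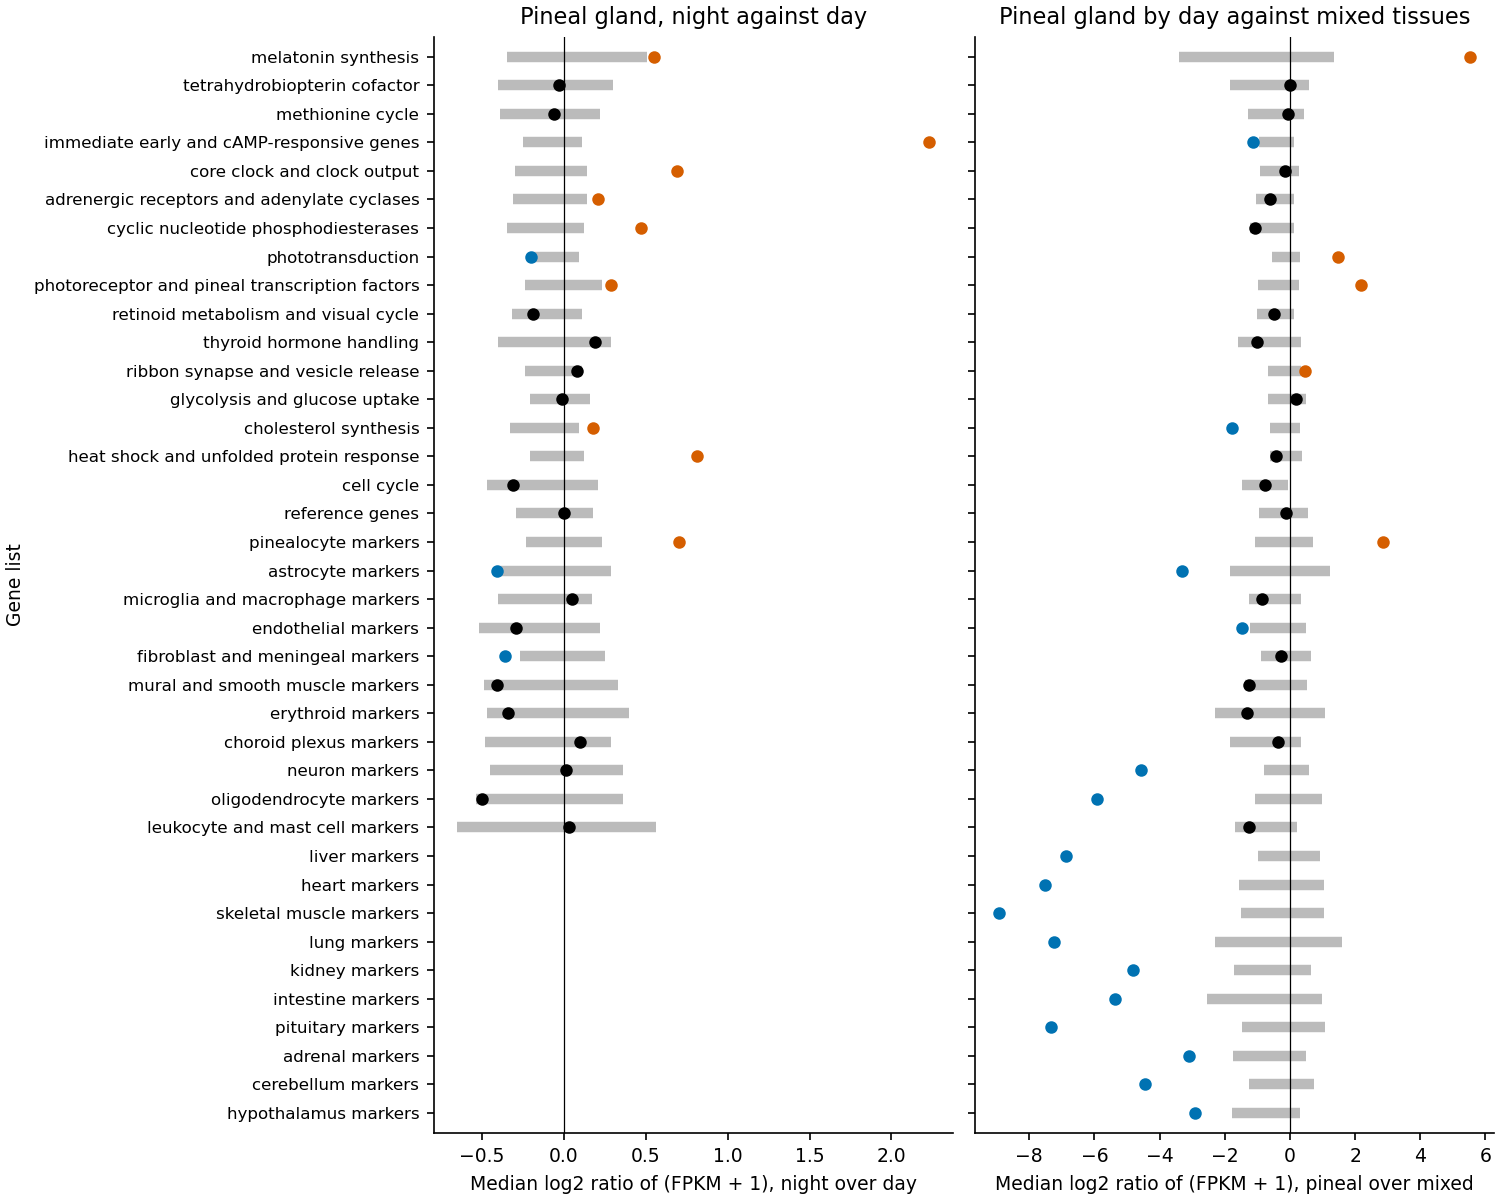
Median log2 ratio of each gene list for night against day and for day against mixed tissues, with the grey bar giving the central 95% of 10000 random lists matched on level; orange and blue points lie above and below it, black points inside. Lists with fewer than 3 members compared are not drawn.

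The counts against the mixed tissues move with the setting: 424 higher and 2611 lower with a pseudocount of 0.1, and 156 and 522 with one of 5. A tissue that is 1 of 15 parts is diluted in the pool, so a ratio to the pool is not a ratio to any single tissue.

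By night the gland stood apart from the mixed tissues through the same enzymes, with Aanat now near the top, although tissue and time differ together in this comparison. Tph1 (log2 11.66), Aanat (762 FPKM and 0.134, log2 9.39; by day log2 2.48), Bsx (493 and 0.0851, log2 8.83), Lhx4 (389 and 0.816, log2 7.75) and Asmt (506 and 1.45, log2 7.69) led the ranking. Fcer1a (235 and 0.461, log2 7.33), Chrnb4 (153 and 0.362, log2 6.82), Pde6c (229 and 1.10, log2 6.78), Gngt2 (log2 6.57) and Gnat2 (log2 6.4) followed. Of 11951 genes and regions compared, 369 were at least 4-fold higher and 1725 lower (median log2 ratio -0.36). Gh1 (-12.52), Alb (-10.99), Scgb1a1 (-10.50), Prl (-10.28), Sftpc and Acta1 (-10 each), Mylpf (-9.46), Ckm (-9.45) and Myl1 (-9.15) were among the lowest on the log2 scale.

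Several lists with night-high members lay higher than in the day comparison. Both comparisons use the same mixed library, so this rise restates the night over day ratios and is not a further result. Fast-responding genes went from a median of -1.14 by day to 0.82 by night (percentile 99.98, 8 of 23 at least 4-fold higher and 0 lower), with Sik1 (97.8 FPKM and 2.86, log2 4.68), Dio2 (76.8 and 2.24, log2 4.59), Crem (428 and 19.7, log2 4.37) and Irs2 (130 and 8.83, log2 3.73). The clock list had a median of 0.55 (percentile 99.9), with Cry2 (63.9 and 13.3, log2 2.18) and Arntl (2.08 and 9.40, log2 -1.75). Chaperones and stress factors reached 0.62 (percentile 99.3, 4 of 22 at least 4-fold higher), with Hspa1a (71.2 and 12.3, log2 2.44) and Ddit3, a factor of the unfolded protein response (90 and 19.5, log2 2.15). Medians of the melatonin list (8.54, percentile 100), pineal transcription factors (2.27, percentile 100), phototransduction (0.63, percentile 99.8), ribbon synapse (0.56, percentile 99.6) and pinealocyte markers (5.17, percentile 100) lay above the range of random lists, and that of cholesterol synthesis (-1.88, percentile 0.01) below.

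The other medians by night were -0.05 for the cofactor list (percentile 72.7), -0.13 for the methionine cycle (59.6), -0.92 for the adrenergic list (5.26), -0.57 for phosphodiesterases (25.5, turning to 0.49 and percentile 99.7 with a filter at FPKM 5), -0.78 for retinoid metabolism (14.1), -0.18 for thyroid hormone handling (61.4), -0.10 for glycolysis (45.7), -1.03 for the cell cycle (28.2, turning to 0.79 for the 2 members left by that filter) and -0.11 for reference genes (60.9). Among cell types they were -3.86 for astrocytes (percentile 0.32), -4.77 for neurons (0.00), -5.93 for oligodendrocytes (0.01), -1.78 for endothelium (1.64), -1.62 for mural cells (2.88, or 2.28 with the libraries centred), -0.63 for fibroblasts (5.28), -1.67 for erythroid cells (5.49), -1.35 for leukocytes (7.5), -0.72 for microglia (18.3) and -0.39 for choroid plexus (59.8). Organ lists ran from -8.81 for skeletal muscle through -7.27 for heart, -7.24 for lung, -7.13 for pituitary, -6.87 for liver, -5.45 for intestine, -4.84 for kidney, -4.50 for cerebellum and -3.18 for the adrenal gland to -3.12 for the hypothalamus.

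Of 11851 genes and regions compared in both tissue comparisons, 270 were at least 4-fold higher by day and 351 by night, and 196 were in both sets. On the lower side 1499 were shared between 1581 and 1725. Independent sets of these sizes would share 8.0 and 230.1, but these sets share the mixed library. With that sharing kept, 100 simulations of unchanged genes gave a mean overlap of 0.0 in both directions. The simulations hold counting error alone, under which 0.0% of unchanged genes pass 4-fold, so they do not cover other variation of the mixed library. Of the unnamed regions, 30 of 87 were at least 4-fold higher in the gland by day, 50 of 105 by night, and 0 lower at either time. The way these regions were chosen is not given, so their direction may reflect that choice.

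Values of 0 or near 0 need care in all 3 libraries. Genes that every cell uses, with examples chosen after their values were seen, such as Gapdh (0.139 FPKM by day, 0.404 by night and 0.0707 in the mixed tissues) and Ppia (0.397, 0.402 and 0.757), were listed near 0, so a low value in these tables can be an estimate that failed. Gnas, the stimulatory G protein alpha subunit, was at 0.123 by day and 0.0799 by night against 22.0 in the mixed tissues, and is uncertain for the same reason.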

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

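Of the tests in this part, the test of scaling and the test of retina carry-over were chosen after the result was seen, and the filter at FPKM 20 after seeing the data. A gene is listed here when it was at least 2-fold below the mixed tissues by day and at least 2-fold above them by night, so that day and night samples lie on opposite sides of the same reference. This difference was not tested, since each group has 1 library. In all, 24 genes and regions met the rule, 23 of them RefSeq genes, and the 10 named by the rule set beforehand had night over day log2 ratios of 7.88 (Slc15a1), 5.73 (Dio2), 5.69 (Dusp1), 5.31 (Irs2), 4.49 (Cited4), 4.01 (Nr4a1), 3.75 (Rgs2), 3.71 (Nr4a3), 2.71 (Pde4d) and 2.23 (Egr1). Of these, 8 belong to the list of fast-responding genes.

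The excess of genes higher by night (66.5% of those at least 2-fold apart, interval 62.7 to 70.1) could come from the shallower night library, which scatters low values more. Among genes with FPKM of at least 20 in the higher library the share was 76.8% (71.4 to 81.4), which argues against depth as the cause among these genes. With a pseudocount of 0.1, which gives low values more weight, the share was 50.7% (47.7 to 53.7) and there was no excess. Scaling could also tilt the split, but under the 3 rescalings the lowest share was 62.0% (58.2 to 65.7), which argues against scaling of that size as the cause. As a hypothesis, the excess is biological and belongs to the night state of the gland, but 1 library per time cannot separate time from differences between dissections or animals.

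The high values of Gnat2 and other cone genes in the gland might be retina carried over, or reads shared with a related gene. Retina rich enough to give the Gnat2 values would bring rod transcripts, yet the pineal to mixed ratio of Gnat1 was 3.67e-05 of that of Gnat2 by day and 2.57e-05 by night, which argues against carry-over. The nearest rod relatives of Gnat2 and Pde6c were low, with Gnat1 at 0.00205 of Gnat2 and Pde6a at 0.00632 of Pde6c by day. This argues against shared reads for Gnat2 and Pde6c. It does not cover the other cone genes: Gngt1, known from rods, was at 1128 FPKM by day against 1053 for Gngt2. Relatives of Gnb3 and Opn1sw were not checked. Expression by pinealocytes remains as a hypothesis and was not tested against cells.

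The low values of genes that every cell uses may come from reads shared with near-identical copies. Over 162 ribosomal protein and respiratory chain genes, Spearman's rho between the number of named copies and the highest FPKM was -0.48, at percentile 0.0 of random pairings. Within the sets, a check added after that value was seen, rho was 0.03 for 80 ribosomal protein genes and 0.1 for 82 respiratory chain genes, so the test cannot tell copies from another property of ribosomal protein genes. Their median highest FPKM was 1.71 against 93.9 for respiratory chain genes. No biological explanation was tested.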

How the results depend on the processing

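The 196 named ratios were rerun with a pseudocount of 0.1, which cannot change a sign, and with the libraries centred, a small shift. They had been chosen as large ratios, so that none changed sign says little about their stability. List medians were rerun under the same settings and with a filter at FPKM 5. No list median outside the range of random lists changed sign under these settings. For list medians inside that range, 18 repeats changed sign, some of them repeats of the same median under different settings. Among them were the adrenergic list by day (-0.60 to 0.37) and phosphodiesterases by night (-0.57 to 0.49) against the mixed tissues with a filter at FPKM 5. With a pseudocount of 0.1 the genes higher and lower by night came to 533 and 518, a share of 50.7% against 66.5%, those higher and lower by day than the mixed tissues to 424 and 2611, and those lower by night than the mixed tissues to 2831. With a pseudocount of 5 the counts higher and lower were 231 and 64 for night against day, 156 and 522 for day against mixed and 207 and 553 for night against mixed. A filter at FPKM 20, chosen after seeing the data, left 208 and 63 for night against day and 570 and 608 lower than the mixed tissues by day and by night. Other size thresholds gave, for night against day at 4-fold, 124 and 11, for day against mixed 993 and 3445 at 2-fold and 92 and 761 at 8-fold, and for night against mixed 1074 and 3724 at 2-fold and 146 and 809 at 8-fold. These shifts follow from what each setting does to low values or to the threshold. The other 58 of 82 counts stayed within 1.5 times. Of 392 repeats of named ratios 371 kept their side of the size threshold and 21 moved past it, and of 328 repeats of list results 319 kept theirs, 6 moved inside the range of random lists and 3 moved out of it. Rescaling shifted the night against day median from -0.11 to -0.01 when centred and the share of genes higher by night to between 62.0% and 75%. Non-overlapping intervals were not run, since the files used here carry no bounds, and the series table gave the same values. Depth limits low values most: at 1 FPKM on 1 kb the night library holds 5.3 fragments.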

Other observations

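In this part, the comparison of regions off gene spans was chosen after the result was seen. Fcer1a was the member of the leukocyte and mast cell list that stood out in the gland (12.9 FPKM by day, 235 by night and 0.461 in the mixed tissues). Other genes of the list gave no such values: Cpa3, a mast cell protease, was at 0.0624 by day and 0 by night, and Ptprc, the pan-leukocyte antigen, at 1.25 and 1.3.

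Unnamed regions span from 231 to 549001 bp, with a median of 17001 bp, and 17 of 157 lie on the span of a gene. Among the lower regions, chosen after their values were seen, PFAR215 (chr8:44565900-44604200) was at 3.30 FPKM by night and 18.5 by day (log2 -2.19) and overlaps the span of Vof16, and PFAR234 (chrX:88578700-88599700) was at 0.822 and 5.77 (log2 -1.89) and overlaps that of P2ry4, both among the genes with the lowest ratios.

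One hypothesis is that regions share transcription with their nearest gene. Across 77 regions within 50 kb of an expressed gene, Spearman's rho between the night over day ratios of region and gene was 0.67, at percentile 100 of random pairings, which fits the hypothesis. Random pairings treat regions as independent, but some share a nearest gene, such as PFAR113 and PFAR114 with Aipl1. The percentile may therefore be overstated. For the 60 regions off gene spans rho was 0.64. Of 45 regions within 50 kb that were at least 2-fold apart, 38 had a nearest gene with a ratio of the same sign, and of the 32 higher ones 14 had a nearest gene at least 2-fold higher. Strand and splice junctions were not analysed here, so extended transcripts and separate ones cannot be told apart.

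Genes of the Hedgehog pathway around Ptch1 (log2 4.27) were looked up after its value was seen and were not tested as a group. Hhip, a Hedgehog-binding protein, was at 25 FPKM by night and 1.45 by day (log2 3.41), Gli2, a transcription factor, at 5.32 and 1.64 (log2 1.26) and Sufu, a repressor of the pathway, at 2.40 and 6.80 (log2 -1.20). Smo, the signal transducer, was at 2.59 and 3.38 (log2 -0.29). Under 1 FPKM at both times were Gli1 (0.159 and 0.133), Gli3 (0.745 and 0.815) and the ligand gene Dhh (0.326 and 0.1), and Shh and Ihh were listed at 0 in the gland.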
